A study of Mus musculus with 6 samples.

How the data were processed

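Whole-kidney RNA from 6 samples was analysed, 3 from littermate controls and 3 from NICD1 mice. NICD1 mice carry Pax8rtTA and TREICNotch1, a pair of transgenes that together allow an inducible Notch1 intracellular domain, the active form of the receptor, to be made in tubule epithelial cells. Each sample was hybridised to its own Affymetrix array. Per the labels' protocols, total RNA was prepared with TRIzol, biotin-labelled with the manufacturer's one-cycle kit, and the raw array values were brought into GeneSpring and normalized there with its RMA16 algorithm. The values deposited by the authors are log2 expression values per probe set after this normalization, ranging from 1.40 to 13.67 on single arrays. RMA subtracts background, forces the arrays to a shared distribution of probe intensities and summarises the probes of a set. It compresses the differences of dim genes, so folds that start or end near the floor are understated, and a shift of all genes in the same direction is largely removed. The version of GeneSpring is not given in the sources used here, and no detection calls, scan dates or array batches are given there either. Scan batch therefore could not be compared with group.

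The table held 34760 probe sets. Of these, 6573 are numbered below the lowest annotated probe set, in the range that array designs of this kind use for control features, and were left out of the main tests. Gene symbols came from the platform annotation supplied with the values, and may be old. 21640 probe sets had 1 symbol, 1321 had several and were not named, and another 5226 outside the control range had none. Entrez identifiers were matched to a mouse gene table of assembly GRCm38.p6 for names only, with 99.6% matched and 0 symbols changed. No coordinates are given because no genome build is named in the files. Each gene was represented by the probe set with the highest mean over all 6 arrays among those with a single symbol, which gave 19937 genes, 954 of them with several probe sets. For 4 of these genes, Acp1, Fggy, Ppp2r5c and Srsf3, different probe sets were called in opposite directions. Members of near-identical gene families, among them Ugt2b38, Cyp4a12a, Slc22a30, Slc22a22, Lyz2 and the ribosomal protein genes with their many pseudogenes, can share probe sequence, so their single values are uncertain to that extent.

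NICD1 and control arrays were compared with limma 3.58.1 in R 4.3.3, a linear model per gene with moderated variances and a two-sided test, with Benjamini-Hochberg adjustment over all genes and an adjusted p threshold of 0.05. All differences are NICD1 minus control on the log2 scale, all SD are over n = 3 arrays, and all adjusted p-values of single genes come from this fit. The same fit over 28187 probe sets outside the control range gave the count of changed probe sets. The 31 gene lists, with 491 genes, were tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, adjusted over the 29 lists with at least 3 measured members. Camera with the correlation estimated from each list, and fry, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, were run beside it. No gene stood in more than 1 list. Of the 491 list genes, 448 were measured. The other 43 were not analysed here, 13 of them because they were named only on probe sets with several symbols. In counts of list members, "adjusted over the list alone" means that the p-values of the list's own genes were adjusted without the other genes.

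The groups, the main test, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes whose 3 NICD1 values all lay on one side of the 3 control values, leaving out predicted genes without an established name. It also named Notch1 with all listed Notch targets, and the up to 4 measured members of each other list with the lowest p. Umod, Havcr1, Slc4a4, Cxcl12, Vegfa, Bnip3, Foxi1, Rbpj and the members of symbol families in the closing section were named after their values were seen. The alternatives were the mean over a gene's probe sets, quantile normalization, centring of arrays on their medians, leaving out the dimmest 40% of genes, a trended and robust variance model, array weights, a minimum change of 2-fold, an adjusted p threshold of 0.01, the replicate number as a block, and leaving out each array in turn. A planned comparison of 3' and 5' probe sets of Gapdh and beta-actin as a check of RNA integrity was not run, because the control-range probe sets carry no names in the tables used here.

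The procedure was tested on simulated arrays of 19937 genes with the means and spread of the real ones, 200 of them changed by known amounts in NICD1 against control. It recovered 27.9% of 68 genes changed by 0.5 log2, 81.8% of 66 changed by 1 log2 and 95.5% of 66 changed by 2 log2, with 5 unchanged genes called. With nothing changed it called 0 genes, and it found the shifted list with 0 of 30 unchanged lists called. The simulated genes varied independently of each other, unlike members of some real lists (estimated correlation 0.49 for the proximal tubule list). The simulation therefore does not test list calls on correlated genes, nor recovery where 32.7% of genes are called. The number of arrays limits the precision. The labels number the samples within each group and call the controls littermates but do not state that each sample came from its own animal, so p-values measure only the spread between these samples, which may be technical. Age, sex and whether controls received the inducer are not given in the sources used here. Figures were drawn with matplotlib 3.10.9.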

Results

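Gene expression was profiled in whole kidneys of 2 groups of mice, 3 littermate controls and 3 NICD1 samples in which an inducible Notch1 intracellular domain was directed to tubule epithelial cells. The series concerns the Notch pathway in clear cell renal cancer, and the comparison addresses what Notch1 activation in the tubule does to the kidney transcriptome. Median log2 expression per array lay between 4.93 and 4.99 in controls and between 5.03 and 5.11 in NICD1 kidneys. Over the 28187 probe sets outside the control range, Pearson correlations of arrays were 0.991 to 0.993 within controls and 0.986 to 0.990 within NICD1, against 0.927 to 0.945 between the groups. These correlations run across probe sets, which are not independent replicates. The first principal component held 84.7% of the variance and separated the groups, with controls between -52.95 and -46.96 and NICD1 arrays between 44.76 and 59.57.

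The 10 named genes with the largest rises in NICD1 kidneys included the listed Notch targets Nrarp, Jag1 and Heyl, Lcn2 of the tubule injury list and Lyz2 of the macrophage list. The 10 with the largest falls included Miox of the proximal tubule list and the male-biased genes Slc7a13, Kap and Slco1a1. Lcn2, a secreted iron-carrier protein that marks tubule injury, rose from 4.47 ± 0.13 to 10.45 ± 0.51 (SD, n = 3), a 63.3-fold difference (5.98 log2, SE 0.22, adjusted p = 2.74e-07). Nrarp, a feedback inhibitor of Notch signalling, rose 50.6-fold, Aldh1a2, which makes retinoic acid, at 33.0-fold, and the cytochrome P450 gene Cyp2f2 at 30.3-fold. Fibrinogen beta chain Fgb rose 19.5-fold, the cadherin Cdh6 19.4-fold, the lipoxygenase Alox15 18.4-fold, the Notch ligand Jag1 16.5-fold, the Notch target Heyl 16.0-fold and the lysozyme Lyz2 15.4-fold. Slc7a13, an amino acid transporter, fell from 11.65 ± 0.14 to 4.35 ± 0.93, a 157-fold difference (-7.30 log2, SE 0.37, adjusted p = 1.56e-06). Large falls were also measured for the organic ion transporter Slc22a30 (149-fold), the androgen-regulated Kap (127-fold), the glucuronosyltransferase Ugt2b38 (115-fold), the organic anion transporter Slco1a1 (110-fold) and the inositol oxygenase Miox (95.1-fold). The methyltransferase Inmt fell 82.8-fold, Ugt3a1 80.4-fold, Slc22a22 77.5-fold and the fatty acid hydroxylase Cyp4a12a 60.8-fold. Levels such as 3.25 for Slc22a30 and 3.03 for Slc22a22 in NICD1 kidneys lay under the median of every array, so these folds are understated where a gene is near the floor and give the genes no firm order. The fallen genes were not equally low in all NICD1 arrays: Kap stood at 5.23, 4.94 and 7.92 in NICD1 replicates 1 to 3, and Ugt3a1 at 3.19, 3.55 and 6.23. All 20 had adjusted p-values of 6.60e-05 or less.

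Across the 19937 genes, 3551 were higher and 2978 lower in NICD1 kidneys at adjusted p under 0.05, together 32.7% of those tested. Of these, 927 were at least 2-fold higher and 1057 at least 2-fold lower, while 45 rose and 132 fell at least 8-fold. All 3 NICD1 arrays lay on one side of all 3 control arrays for 8651 genes, or 43.4%, where chance gives 10%. Among probe sets, 7968 changed, 4464 upward and 3504 downward, including 442 higher and 333 lower without a gene symbol. Centring each array on its median moved the median difference of all genes from 0.015 to -0.091 and the balance of calls to 2619 higher and 3710 lower, so the higher share went from 54.4% to 41.4%. Calls of genes near the threshold therefore depend on this choice. Among named genes, centring ended the calls of Umod and Cd3e and made those of Slc4a4 and Havcr1, both as lower.

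Notch1 itself was higher in every NICD1 array, at 10.19 ± 0.18 against 6.56 ± 0.11 in controls, a 12.4-fold difference (3.63 log2, SE 0.12, adjusted p = 1.52e-07). The value comes from a single probe set, whose position relative to the transgene is not known here, so it does not separate transgene from endogenous transcript. Of 13 Notch targets, 12 rose, 0 fell and Hes5 did not pass, and 12 rose when adjusted over the list alone. The list's median difference was 2.04 log2 (camera adjusted p = 1.32e-11, and adjusted p = 0.0426 with an estimated correlation). Nrarp went from 4.81 ± 0.30 to 10.47 ± 0.08, Jag1 from 6.56 ± 0.18 to 10.61 ± 0.05 and Heyl from 4.93 ± 0.58 to 8.93 ± 0.19. The receptor Notch3 rose by 2.25 log2, the transcriptional repressors Hey2, Hes1 and Hey1 by 2.20, 1.73 and 1.56, Myc by 2.20, the progenitor-associated factor Sox9 by 2.04 and the cyclin Ccnd1 by 1.97. Dtx1 and Lfng rose by 0.84 and 0.77 log2, and Hes5 differed by 0.22 (adjusted p = 0.232). Of 27 measured Notch receptors, ligands and processing genes, 10 rose, 3 fell and 14 did not pass, with 11 and 3 when adjusted over the list alone. Among the risen were Maml3 (1.28 log2), Notch2 (1.06), Maml2 (1.05) and Rbpj (0.86), the last encoding the DNA-binding partner of the Notch intracellular domain. As a list they did not pass camera (median 0.16, adjusted p = 0.09997), but the adjusted p was 0.0423 without NICD1 replicate 3.

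**Figure D1:**
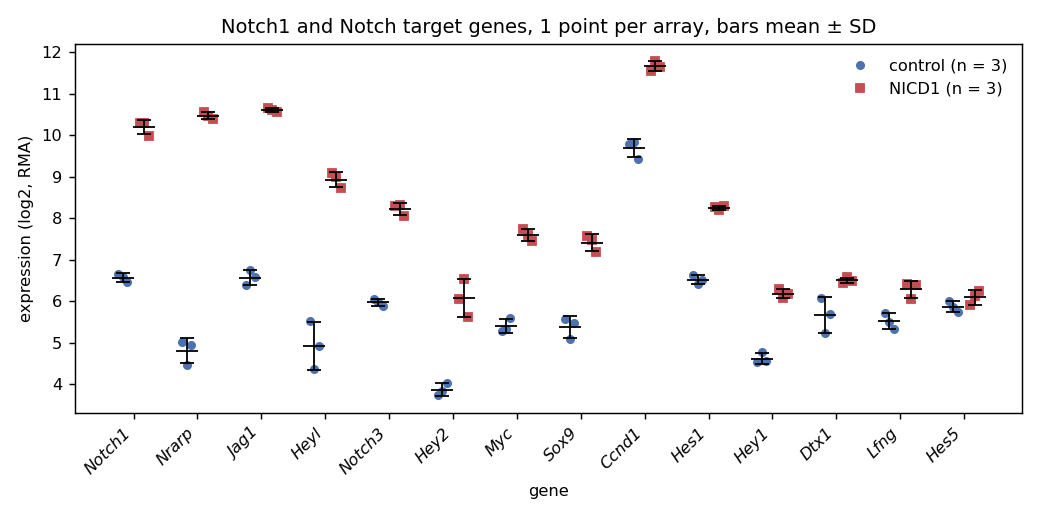
Log2 RMA expression of Notch1 and 13 Notch targets (x axis) in single arrays, 3 control (circles) and 3 NICD1 (squares), with mean ± SD as bars. NICD1 arrays lie above all controls for Notch1 and the targets except Hes5, with the widest gap for Nrarp.

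Genes that mark the proximal tubule fell almost throughout, and those of the loop of Henle, distal tubule and acid-base regulating intercalated cells mostly fell with them. Of 35 measured proximal tubule genes, 33 fell, 0 rose and 2 did not pass, and 34 fell when adjusted over the list alone. Their median difference was -2.83 log2 (camera adjusted p = 3.32e-26, and adjusted p = 0.115 with an estimated correlation). The organic anion transporter Slc22a8 went from 10.16 ± 0.18 to 4.75 ± 0.34 (-5.41 log2), the neutral amino acid transporter Slc6a19 from 9.69 ± 0.25 to 4.83 ± 0.22 (-4.85), the glucose transporter Slc2a2 from 9.01 ± 0.03 to 5.75 ± 0.27 (-3.26) and the phosphate transporter Slc34a3 from 7.53 ± 0.05 to 4.92 ± 0.17 (-2.61). The bicarbonate cotransporter Slc4a4 differed by only -0.25 (adjusted p = 0.126), although it passed as lower after centring of the arrays (-0.36). Of 17 genes of the loop of Henle and distal tubule, 13 fell, 1 rose and 3 did not pass, with the same counts when adjusted over the list alone (median -1.56 log2, camera adjusted p = 5.31e-09, and adjusted p = 0.0426 with an estimated correlation). Egf fell from 11.38 ± 0.10 to 5.49 ± 0.39 (-5.88 log2), and the calcium-binding proteins Calb1 and Pvalb and the FGF23 co-receptor Kl fell by 4.15, 3.41 and 2.68 log2. The gene that rose was Umod, the main urinary protein, at 12.08 ± 0.11 against 12.41 ± 0.08 in NICD1 (0.32, adjusted p = 0.0403). That call was lost without control replicate 1 (0.30), control replicate 3 (0.28), NICD1 replicate 1 (0.29) or NICD1 replicate 2 (0.31), and after centring (0.22).

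In the collecting duct, intercalated cell genes fell and principal cell genes moved both ways. Of 15 intercalated cell genes, 11 fell, 0 rose and 4 did not pass, and 13 fell when adjusted over the list alone (median -1.74 log2, camera adjusted p = 4.30e-10, and adjusted p = 0.0786 with an estimated correlation). The anion exchanger Slc26a4 fell from 7.33 ± 0.12 to 3.95 ± 0.12, while Slc4a9, the proton pump subunit Atp6v1g3 and Slc4a1 fell by 2.49, 2.38 and 2.05 log2. Foxi1, a transcription factor needed for intercalated cells, fell by 1.48 log2. Of 12 principal cell genes, 2 rose, 3 fell and 7 did not pass, with the same counts when adjusted over the list alone. The list did not pass camera (adjusted p = 0.882), its median was 0.094 (-0.011 after centring) and its mean -0.14, and the direction of its test turned under quantile normalization and under centring. Members moved apart: the sodium channel subunits Scnn1g and Scnn1b rose by 1.23 and 0.86 log2, and the water channels Aqp3 and Aqp2 fell by 2.52 and 1.05 log2. The call of Aqp2 was lost without control replicate 1 (-0.93), and that of Scnn1b without control replicate 2 (0.82) or 3 (0.83), while its difference was 0.57 without NICD1 replicate 1.

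Genes of mitochondrial energy metabolism, which the proximal tubule uses heavily, fell together. All 23 measured genes of the tricarboxylic acid cycle and respiratory chain fell, as did all 23 when adjusted over the list alone (median -1.12 log2, camera adjusted p = 8.46e-17, and adjusted p = 0.0426 with an estimated correlation). Cytochrome c (Cycs) fell from 10.35 ± 0.04 to 8.68 ± 0.16 (-1.67 log2), Ndufs1 by 1.62 and Ndufa9 by 1.54, and the succinyl-CoA ligase subunit Sucla2 went from 9.35 ± 0.13 to 7.84 ± 0.01. Of 23 fatty acid oxidation genes, 22 fell, 0 rose and 1 did not pass, with 22 when adjusted over the list alone (median -1.25 log2, camera adjusted p = 2.51e-15, and adjusted p = 0.107 with an estimated correlation). The peroxisomal enzyme Ehhadh fell from 10.60 ± 0.05 to 7.08 ± 0.49 (-3.52 log2), and the mitochondrial Acadm, Cpt2 and Acads fell by 2.16, 2.07 and 1.66 log2. These genes moved with the proximal tubule markers. Genes of hypoxia, glycolysis and clear cell renal cancer did not move as a group. Of 22 measured, 6 rose, 5 fell and 11 did not pass, with 7 and 5 when adjusted over the list alone (median -0.11, mean 0.012, camera adjusted p = 0.977). The direction of that test turned under several alternatives, both other scalings and fry among them. The list joins several programmes, and opposed moves of its members cancel in a test of the whole, so a change of 1 programme is not excluded. The glycolytic enzymes Pfkp, Hk2 and Hk1 rose by 1.37, 1.02 and 0.87 log2 and the glucose transporter Slc2a1 by 0.73, while the angiogenic factor Vegfa fell by 0.51 and the mitophagy gene Bnip3 by 1.30.

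Genes of tubule injury, proliferation and extracellular matrix were higher in NICD1 kidneys. Of 18 tubule injury genes, 16 rose, 0 fell and 2 did not pass, with 16 and 1 when adjusted over the list alone (median 2.03 log2, camera adjusted p = 8.78e-12, and adjusted p = 0.111 with an estimated correlation). Beside Lcn2, the hyaluronan receptor Cd44 rose from 3.94 ± 0.29 to 7.61 ± 0.48 (3.67 log2), Clu by 2.79 and Anxa2 by 2.53. Havcr1, the kidney injury molecule, stood at 3.71 ± 0.19 in controls and 3.37 ± 0.19 in NICD1 (-0.34, adjusted p = 0.0890) and passed as lower without NICD1 replicate 3 (-0.45) and after centring (-0.45). Both levels lay under the median of every array, and without detection calls it is open whether the gene was detected in either group. All 25 measured cell cycle genes rose, and all 25 did so when adjusted over the list alone (median 1.75 log2, camera adjusted p = 3.11e-17, and adjusted p = 0.111 with an estimated correlation). The replication helicase subunit Mcm6 rose from 4.10 ± 0.12 to 7.71 ± 0.23 (3.61 log2), the cyclins Ccna2 and Ccnb2 by 2.90 and 2.17, and the mitotic kinesin Kif11 by 2.15. Of 35 genes of extracellular matrix and fibroblasts, 30 rose, 0 fell and 5 did not pass, with 30 and 1 when adjusted over the list alone (median 1.09 log2, camera adjusted p = 1.09e-11, and adjusted p = 0.233 with an estimated correlation). Col1a1 rose from 7.19 ± 0.22 to 10.15 ± 0.27 (2.96 log2), Fn1 by 2.84, and the basement membrane genes Lama1 and Col4a1 by 2.58 and 2.21.

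Some arrest and stress genes rose and none of those measured fell. Of 10 genes of p53 and cell cycle arrest, 6 rose, 0 fell and 4 did not pass, with 7 when adjusted over the list alone (median 0.43 log2, camera adjusted p = 0.000792, and adjusted p = 0.126 with an estimated correlation). The kinase inhibitors Cdkn2b and Cdkn1b rose by 1.31 and 0.69 log2, Phlda3 by 1.07 and Trp53inp1 by 0.71. Of 13 immediate early genes, which respond within minutes to stress and handling, 5 rose, 0 fell and 8 did not pass, with 5 when adjusted over the list alone (median 0.54 log2, camera adjusted p = 0.00357, and adjusted p = 0.431 with an estimated correlation). Egr1, Atf3, Jun and Ier2 rose by 2.01, 1.60, 1.47 and 1.01 log2. Kidney development and epithelial to mesenchymal transition genes did not pass camera as lists, although the second list passed fry in the upward direction. That list holds epithelial and mesenchymal genes, which a transition would move in opposite directions, so neither test can show or exclude one. Of 14 kidney development genes, 4 rose, 2 fell and 8 did not pass, with the same counts when adjusted over the list alone (median 0.050, camera adjusted p = 0.414). The sign of that median turned under quantile normalization (-0.012) and centring (-0.056). The risen members were Pax8 (1.41 log2), Wnt11 (0.86), Emx2 (0.81) and Wnt4 (0.73). Pax8 is also the gene named in the Pax8rtTA transgene. Of 12 genes of epithelial to mesenchymal transition, 4 rose, 2 fell and 6 did not pass, again with the same counts when adjusted over the list alone (median 0.13, camera adjusted p = 0.450). The members with the lowest p were epithelial: Epcam, Cdh1 and the junction protein Tjp1 rose by 1.30, 1.23 and 0.82 log2, and the kidney cadherin Cdh16 fell by 1.11.

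Myeloid cell and antigen presentation genes rose, and lymphocyte genes did not rise as a group. Of 18 genes of macrophages and dendritic cells, 17 rose, 0 fell and 1 did not pass, with 17 when adjusted over the list alone (median 1.67 log2, camera adjusted p = 1.54e-09, and adjusted p = 0.233 with an estimated correlation). Lyz2 rose from 5.26 ± 0.51 to 9.20 ± 0.61 (3.94 log2), the protease Ctss by 3.79, the lipopolysaccharide co-receptor Cd14 by 2.79 and the integrin Itgam by 2.41. Of 11 antigen presentation genes, 10 rose, 0 fell and 1 did not pass, with 10 when adjusted over the list alone (median 1.51 log2, camera adjusted p = 1.74e-07, and adjusted p = 0.169 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 rose by 2.62 and 1.55 log2, the immunoproteasome subunit Psmb8 by 2.11 and B2m by 1.51. Of 18 cytokines and chemokines, 13 rose, 1 fell and 4 did not pass, with 14 and 2 when adjusted over the list alone (median 0.69 log2, camera adjusted p = 6.30e-05, and adjusted p = 0.0788 with an estimated correlation). The chemokines Cxcl10, Ccl5 and Cxcl16 and the adhesion molecule Icam1 rose by 2.55, 2.37, 1.05 and 1.72 log2, and Cxcl12 was the gene that fell (-1.93). Of 10 interferon response genes, 7 rose, 0 fell and 3 did not pass, with 9 when adjusted over the list alone (median 1.21 log2, camera adjusted p = 0.00108, and adjusted p = 0.461 with an estimated correlation). Irf7, Oasl2, Rtp4 and Ifih1 rose by 2.20, 2.11, 2.08 and 1.80 log2, with the highest value of each in NICD1 replicate 1. Leaving out each array in turn, their lowest differences were 1.72, 1.75, 1.47 and 1.41 log2.

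Of 13 lymphocyte genes, 2 rose, 1 fell and 10 did not pass, with 1 and 1 when adjusted over the list alone. The median was -0.011 and the mean 0.064, and camera (adjusted p = 0.958) gave a downward and fry an upward direction. The co-receptor Cd8a, which dendritic cells also carry, rose by 1.38 log2, the T cell receptor component Cd3e by 0.30, and the B cell gene Ms4a1 fell by 0.45, while Cd79b differed by -0.22 (adjusted p = 0.301). The call of Cd3e (adjusted p = 0.0456) was lost without control replicate 2 (0.26), control replicate 3 (0.28) or any NICD1 replicate (0.30 in each case), under both other scalings (0.19 and 0.20) and with the trended variance model, and that of Ms4a1 without control replicate 2 (-0.32) or NICD1 replicate 2 (-0.44).

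Of 12 endothelial genes, 5 fell, 0 rose and 7 did not pass, with 5 fallen when adjusted over the list alone (median -0.63 log2, camera adjusted p = 0.00391, and adjusted p = 0.431 with an estimated correlation). The angiopoietin receptor Tek fell by 1.76 log2, the VEGF receptor Kdr by 1.54, the glomerular endothelial marker Ehd3 by 0.89 and Tie1 by 0.65. Of 7 podocyte genes, 2 rose, 4 fell and 1 did not pass, with 2 and 4 when adjusted over the list alone (median -0.39, camera adjusted p = 0.224). Podxl, Ptpro and Nphs1 fell by 1.74, 0.97 and 0.93 log2, and the actin-associated Synpo rose by 1.09. Markers of neighbouring tissues showed no called member in either direction. All 6 perirenal fat genes (median -0.068, camera adjusted p = 0.882), all 6 adrenal genes (median -0.050, camera adjusted p = 0.768) and all 6 skeletal muscle genes (median 0.061, camera adjusted p = 0.958) did not pass in limma's test, and 0 of each passed when adjusted over the list alone. The median of the muscle list was -0.037 under quantile normalization and -0.045 under centring. Their lowest p-values belonged to Fabp4, Ucp1, Plin1 and Cidec in fat (-0.45, 0.16, -0.11 and 0.17 log2), to Cyp21a1, Cyp11a1, Hsd3b1 and Cyp11b1 in the adrenal list (-0.21, -0.11, -0.11 and 0.052) and to Myl1, Myh4, Acta1 and Mylpf in the muscle list (-0.12, 0.092, 0.092 and 0.080). Only 2 red blood cell genes were measured, Alas2 and Slc25a37, both of which fell, by 1.69 and 0.74 log2, also when adjusted over the list alone.

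Male-biased genes of the mouse kidney fell, and sex-linked genes did not pass. All 7 male-biased kidney genes fell, as did all 7 when adjusted over the list alone (median -4.46 log2, camera adjusted p = 2.89e-08, and adjusted p = 0.111 with an estimated correlation). They were led by Slc7a13, Kap and Slco1a1, with Cyp2j13 at -4.46 and Cyp2e1 at -4.26 log2. Of 4 sex-linked genes, 0 rose and 0 fell, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.589). Xist stood at 2.80 ± 0.08 in controls and 2.97 ± 0.13 in NICD1, Uty at 7.37 ± 0.12 and 7.52 ± 0.12, Eif2s3y at 7.69 ± 0.07 and 7.45 ± 0.46, and Kdm5d at 6.19 ± 0.05 and 6.52 ± 0.18. Kdm5d passed as higher without NICD1 replicate 3 (0.44 log2), with array weights (0.38) and without the dimmest genes (0.33), and Eif2s3y passed as lower without NICD1 replicate 1 (-0.48). Of the 2 female-biased genes measured, Cyp4a14 fell by 1.72 log2, and Slc7a12 differed by 1.60 (adjusted p = 0.0737) and rose when adjusted over the list alone. Control replicate 1 held the highest Slc7a12 value of the controls, 7.33 against 4.56 and 4.86, and without it the difference was 2.48 (adjusted p = 0.000107). It also passed with array weights (1.80, adjusted p = 0.0294). Of 12 circadian clock genes, 2 rose, 3 fell and 7 did not pass, with the same counts when adjusted over the list alone (median -0.092, camera adjusted p = 0.450). Arntl rose by 0.95 log2, and its antiphase outputs Ciart, Dbp and Tef fell by 1.85, 1.31 and 1.05 log2. Opposed moves cancel in a test of the list, so its camera result does not bear on clock phase. Among controls, replicate 1 lay nearest the NICD1 arrays, with Dbp at 7.83 against 8.84 and 9.13 and Arntl at 4.67 against 4.14 and 4.15. Time of day at collection was not compared between the groups.

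With the preset correlation, 17 of the 29 lists passed camera, and 3 of them held with an estimated correlation: Notch targets, the loop of Henle and distal tubule, and the tricarboxylic acid cycle and respiratory chain. In fry, which does not compare a list with other genes, 19 passed. These included 3 that had not passed camera, the Notch receptors, ligands and processing genes (adjusted p = 0.00367), podocytes (0.00999) and epithelial to mesenchymal transition (0.0129), while the interferon response did not pass (adjusted p = 0.0587).

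**Figure D2:**
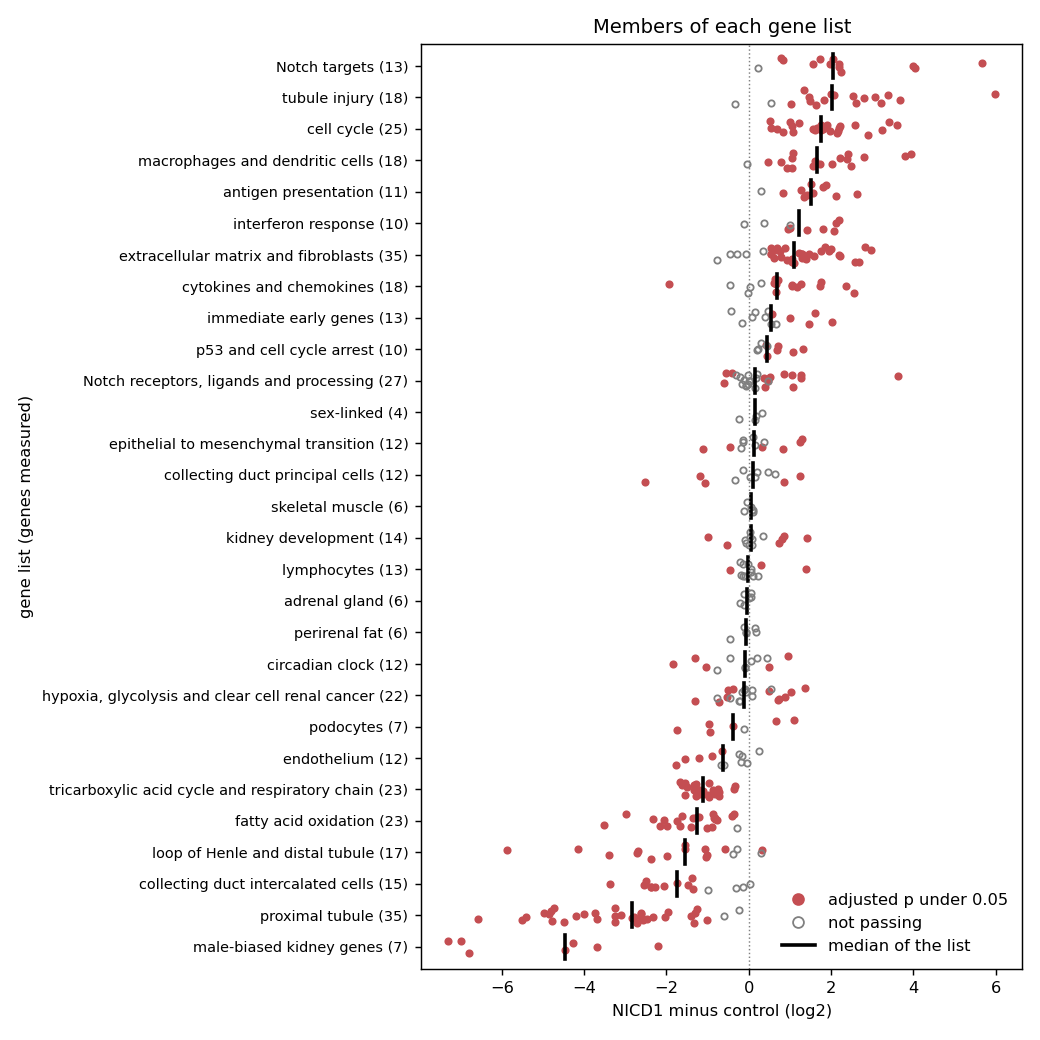
Difference between NICD1 and control (x axis, log2) of each measured member of 29 gene lists (y axis, members measured in brackets), with filled red points at adjusted p under 0.05, open points otherwise and a black bar at the list's median. The male-biased (median -4.46) and proximal tubule lists (-2.83) lie furthest left and the Notch target (2.04) and tubule injury lists (2.03) furthest right, while the principal cell, hypoxia and skeletal muscle lists lie near 0 and their tests turn direction under other scalings.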

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

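The test of the control-range probe sets was added only after the data were seen, while the regrouping of the arrays was planned. Probe sets outside the gene comparisons, numbered in the range used for control features, were drawn to attention because 33 of the 6573 were higher in NICD1 than in the control arrays. Another 17 were lower, and the median difference over all of them was 0.0873 log2. What these probe sets measure is not known here.

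The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 3551 genes higher and 2978 lower, 1 of the 10 splits with counts as large, and the highest other split gave 0 genes on its larger side. For probe sets, 1 of the 10 splits reached the real 7968 changed, and the highest other gave 0. For gene lists, 3 of the 10 splits gave as many passing lists as the real 17, and the highest other also gave 17. Every other split passed at least 11 lists while calling 0 genes and 0 probe sets. The number of lists passing camera at the preset correlation therefore does not single out the real groups. Each of the other splits puts 2 arrays of a group with 1 of the other, so it keeps part of the group difference and is not a comparison without one.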

How the results depend on the processing

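All alternatives were planned, but Umod, Havcr1, Slc4a4, Cxcl12, Vegfa, Bnip3, Foxi1, Rbpj and the family members were named, and so tested under them, only after the results were seen. Of 159 named genes, 138 were called. Of these, 133 kept their call under all alternatives run for single genes, which leave out the 2-fold minimum and the threshold of 0.01, 5 lost it under at least 1 (Umod, Cd3e, Aqp2, Scnn1b and Ms4a1) and 0 reversed. Counts of genes and probe sets stayed within 1.5 times under all alternatives except a minimum change of 2-fold, which by construction left 927 genes higher, 1057 lower and 2489 probe sets. Without each array in turn, 2816 to 3488 genes were higher and 2459 to 2811 lower. Same-numbered samples of the groups deviated from their group means with correlations of -0.0687, -0.0115 and -0.0702, so no shared deviation was visible. Deviations from the mean of so small a group depend on each other. A lack of shared deviation therefore cannot decide whether the numbers pair samples. With the replicate block, 3219 genes were higher and 2762 lower, with 7119 probe sets and 17 lists. The block ended the calls of Cd3e and Umod and made that of Slc7a12 among named genes.

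With an estimated correlation, 3 lists passed. Calls lost were those of proximal tubule (adjusted p = 0.115), intercalated cells (0.0786), endothelium (0.431), tubule injury (0.111), matrix (0.233), macrophages (0.233), antigen presentation (0.169), cytokines (0.0788), interferon (0.461), cell cycle (0.111), p53 (0.126), fatty acid oxidation (0.107), immediate early (0.431) and male-biased genes (0.111). Fry lost the interferon list (0.0587) and turned lymphocytes (0.844) and hypoxia (0.163).

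Reversals concerned results that did not pass in any of these settings, and their cause was not tested. Test directions turned under quantile normalization for principal cells (adjusted p = 0.966), hypoxia (0.901) and muscle (0.862), and under centring for the same lists (0.921, 0.906 and 0.921). Without the dimmest genes they turned for lymphocytes (0.217) and hypoxia (0.935), and with array weights for hypoxia (0.855) and fat (0.890). Without each array in turn, adjusted p ranged from 0.436 to 0.936 for principal cells, 0.756 to 0.997 for lymphocytes, 0.688 to 0.997 for hypoxia, 0.531 to 0.865 for fat and 0.834 to 0.951 for muscle. Among genes, Acta1 turned to -0.034 under quantile normalization, and Cyp11b1 (-0.054), Myh4 (-0.014), Acta1 (-0.014) and Mylpf (-0.026) did so under centring. Without each array, Cidec ranged from -0.053 to 0.50, Plin1 from -0.29 to 0.065, Cyp11b1 from -0.049 to 0.13, Mylpf from -0.054 to 0.19, Ucp1 from -0.053 to 0.28 and Fabp4 from -0.78 to 0.14. Signal over background limits dim genes, as no detection calls were used.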

Other observations

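The families and the tests of explanations below were all chosen after the results were seen. Symbol families of the cytosolic and the mitochondrial ribosome moved in opposite directions. Among 236 groups of genes that share a symbol stem and have at least 10 measured members, 29 of 36 genes of the large cytosolic subunit (Rpl) rose and 1 fell, with a median of 0.78 log2 (camera adjusted p = 1.24e-09, and adjusted p = 0.421 with an estimated correlation). Of 31 genes with the stem of the small cytosolic subunit (Rps), 23 rose and 0 fell (median 0.83, camera adjusted p = 1.71e-07, and adjusted p = 0.443 with an estimated correlation). The stem was matched by symbol alone, so genes named Rps6k, which encode kinases and not subunits, are not kept apart. Rpl36a rose from 8.32 ± 0.04 to 9.86 ± 0.17 (SD, n = 3), Rps12 by 1.47 log2 and Rps20 by 1.44. Of 48 genes of the large mitochondrial subunit (Mrpl), 39 fell and 2 rose (median -0.56, camera adjusted p = 8.06e-11, and adjusted p = 0.421 with an estimated correlation), and of 29 of the small subunit (Mrps), 23 fell and 0 rose (median -0.54, camera adjusted p = 7.97e-09, and adjusted p = 0.398 with an estimated correlation). Mrps21 fell by 1.30 log2 and Mrpl50 by 1.06. Each of these 4 medians kept its direction under quantile normalization and under centring of the arrays.

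Some other transport and metabolic families fell as well. Not all did: of 21 Aldh genes 4 rose and 10 fell (camera adjusted p = 0.0615), and the Sult family did not pass either (camera adjusted p = 0.349). With an estimated correlation, the lowest adjusted p of any family was 0.373. Of 23 organic ion transporters of the Slc22 family, 15 fell and 1 rose, with a median of -2.50 log2 (camera adjusted p = 1.24e-09, and adjusted p = 0.398 with an estimated correlation), and Slc22a19 fell from 9.52 ± 0.23 to 3.89 ± 0.19. Of 13 acyl-CoA thioesterases (Acot), 10 fell and 1 rose (median -1.37, camera adjusted p = 7.33e-06, and adjusted p = 0.443 with an estimated correlation), with Acot4 at -2.60. Of 14 peroxisome biogenesis genes (Pex), 12 fell and 0 rose (median -0.74, camera adjusted p = 2.67e-05, and adjusted p = 0.421 with an estimated correlation). Among families that went up, 13 of 20 nuclear pore genes (Nup) rose and 0 fell (median 0.53, camera adjusted p = 7.34e-05, and adjusted p = 0.499 with an estimated correlation), led by Nup210 at 1.83 log2. The 10 Toll-like receptors had a median control level of 3.99, under the median of every array. Of these, 7 rose and 0 fell (median 0.70, camera adjusted p = 0.00592, and adjusted p = 0.529 with an estimated correlation), with Tlr13 at 1.66. These directions also held under both other scalings.

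The fall of the proximal tubule genes was weighed against 3 technical or compositional explanations. A uniform dilution of tubule RNA would lower all well-expressed members by about the same amount, but over the 29 members with a control level of at least 9 the differences ran from -0.25 (Slc4a4) to -6.57 (Miox), with an SD of 1.543 against a median standard error of 0.2307. These unequal falls speak only against a uniform dilution, not against an uneven loss of tubule cells. A lower share of tubule cells with no other change would raise the markers of the other cell types alike. The matrix list lay 1.719 log2 above the endothelium list in the median (permutation p = 1e-05, the smallest that 100000 resamples can give). A change of either list for its own reasons would open this gap at any share of tubule cells, so it cannot tell whether that share fell. Permutations here and below run across genes and ignore the correlation between them. Within single arrays, relative to the control means, the gap between these 2 lists was 1.58 to 1.70 in NICD1 and -0.043 to 0.094 in controls. Here and below, controls lie near 0 by construction, so their gaps show only the spread between arrays. The NICD1 gaps restate the same difference array by array. Rescaling the deposited values did not remove the fall of the proximal tubule genes, with a list median of -2.934 after centring and -2.781 after quantile normalization. Centring moves all genes of an array by the same amount, so it could hardly have undone so large a fall. Both rescalings start from values already normalized with RMA, so neither tests that step. A loss of differentiated tubule gene expression under Notch1 activation, with or without some loss of tubule cells, may contribute and was not tested.

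All male-biased kidney genes fell, a pattern that a difference in sex between the groups could give. Xist differed by 0.1743 log2, and the lowest Y-linked difference was -0.2371 (Eif2s3y), both far below what such a difference would need, with Xist near the floor and Y-linked genes well above it in every array. The male-biased genes may instead simply share the fall of the proximal tubule, where several of them are made. Their median lay 1.63 log2 lower than that of the proximal tubule list (difference -1.63, permutation p = 0.0750, and at most p = 0.0827 without each of the 7 members in turn). The gap within single arrays ran from -2.57 to -1.42 in NICD1 and from -0.088 to 0.12 in controls. These gaps restate the same difference array by array and show only that it was present in each NICD1 array. The permutation across genes did not pass, and whether 7 genes stand for their class is another question. A shared fall and a separate loss of male-biased expression therefore cannot be told apart here.

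Intercalated cell genes fell while principal cell genes moved both ways. A loss of the collecting duct as a whole would lower both lists alike, but their medians differed by -1.839 log2 (permutation p = 0.00861 across genes), and within single arrays the gap was -2.25 to -1.59 in NICD1 and -0.19 to 0.25 in controls. These values were part of the pattern as first seen, so they argue against an equal loss of both cell types but lend the pattern no independent support. No single array decided this, since the difference stayed between -2.114 and -1.552 without each array in turn. Whether the number of either cell type or the expression per cell changed was not tested.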
